A study of Mus musculus with 12 samples.

How the data were processed

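RNA was sequenced in 12 libraries of 3T3-L1 adipocytes in 4 groups of 3: empty vector, Foxp1 overexpression, scrambled hairpin RNA and hairpin RNA against Foxp1. Per the labels' protocols, cells were differentiated in 1 µM dexamethasone, 0.5 mM isobutylmethylxanthine, 5 µg/ml insulin and 10 µM troglitazone, kept in 5 µg/ml insulin only from day 4 and in growth medium from day 6. The day of harvest, the species and untranslated regions of the overexpression construct, the strand setting and what a replicate is (a dish, a transduction or a library) are not stated. Total RNA was extracted with TRI reagent and RNeasy columns and made into libraries by Illumina protocols, per the labels' protocols.

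The values start from RPKM that the authors computed per gene and library; this is the unit of the deposited matrix. Per the submitters' processing notes, the tools were HISAT2 2.1.0 and featureCounts of Subread 1.5.3 on build mm10; their roles and settings, including the treatment of reads matching several places, are not given. The deposited numbers were RPKM divided by 1000, as shown by their sums of 311.82 to 357.68 per library and by the value of 1 read, and were multiplied by 1000 here. Gene identifiers are of Ensembl release 98, and symbols, positions and exon lengths were taken from GENCODE M21 on the same assembly, GRCm38, for 28896 of 28948 identifiers. Where a symbol belonged to several identifiers, as for Aldoa, the more highly expressed was used in the lists.

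Depth was read from the values. Value times exon length came out as a whole multiple of a fixed step, within 0.05 of a read, for 98.83% to 98.93% of values above 0 per library, which gives 35252019 to 38450002 assigned reads. These recovered reads were used for depth and for the voom alternative only.

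Genes with at least 1 RPKM in at least 3 libraries were kept (11245). Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend of the variance with expression), in a single model of 4 groups, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A fold change on this scale understates that of low genes, so ratios of mean RPKM are given where sizes matter. The contrasts were overexpression against empty vector, knockdown against scrambled hairpin, the difference of these responses, and scrambled hairpin against empty vector. No shared controls enter the first pair of contrasts. Values are means ± SD over 3 libraries.

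Before the data were examined, 30 gene lists were fixed, on metabolism, fat cell state, stress, proliferation, other cell types and RNA quality, and 26 with at least 5 measured members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. Named genes were also chosen by a rule fixed then: the Foxp and Foxk genes; up to 8 glycolytic genes per comparison and up to 3 per other list, smallest adjusted p first; the 5 largest rises and falls per comparison with at least 5 RPKM on average and no overlap (3 for the controls); and 5 genes each with opposite and with the same calls. Not every gene the rule picked is given in the text. Pfkm, Gapdh, Sqle and Slc2a4 in overexpression and Cyp51 in knockdown were named after their values were seen. So were 7 further lists and the gene classes of the closing section, and the patterns weighed there were picked after looking also at transcript classes, transcript lengths, processed pseudogenes, the deviation of overexpression replicate 3 and a hypoxia-like axis between the controls.

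The test was tested on simulated data made from the real means and spread with known changes (negative binomial reads). For overexpression (11065 genes), 17 of 50 genes changed by 1.2-fold were called, 48 of 50 at 1.5-fold, 50 of 50 at 2-fold and 50 of 50 at 4-fold, with 7 of 10865 unchanged genes called. For knockdown (11150 genes), 11 of 50, 44 of 49, 49 of 50 and 49 of 50 were called, with 5 of 10951 unchanged genes called.

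Alternatives fixed before the data were examined were other pseudocounts and filters, 3 scalings, only the libraries compared, 2 variance models, 2 stricter thresholds, a block for the replicate number, other list tests and leaving out each library. Rescaling to reads outside the mitochondrial genome and voom were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.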

Results

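The data are RNA levels per gene of 3T3-L1 adipocytes in which the transcription factor Foxp1 was raised or lowered. 3T3-L1 is a fibroblast-like line from mouse embryos that turns into fat cells under dexamethasone, isobutylmethylxanthine, insulin and, here, troglitazone. There were 4 groups of 3 libraries each. Cells overexpressing Foxp1 were compared with cells carrying an empty vector, and cells with a short hairpin RNA against Foxp1 were compared with cells carrying a scrambled hairpin. The 12 libraries held 35252019 to 38450002 reads assigned to genes, so that 1 read in a gene of 1 kilobase was worth 0.026 to 0.0284 RPKM (reads per kilobase of exon, scaled to library size). Of 28948 genes listed, 11245 were tested. List counts are given over all genes, and adjusted over the list alone where that differs. Replicates of a group correlated at 0.9972 or more on log2(RPKM + 1) across all 28948 listed genes, including those too low to test. Squared differences between replicates were 2.73 to 31.81 times those of read sampling, averaged over genes with at least 20 reads in the pair. Mitochondrial transcripts took 9.02% ± 0.39 of reads in the empty vector group, 10.9% ± 1.9 with overexpression, 5.36% ± 0.49 in the scrambled group and 6.33% ± 0.43 with knockdown (SD, n = 3 each). Overexpression replicate 3 stood apart from its group, with a mitochondrial share of 13.09% beside 9.98% and 9.63%. Its squared differences from replicates 1 and 2 were 30.52 and 31.81 times read sampling, beside 6.03 between replicates 1 and 2.

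Foxp1 itself followed the labels in every library. It lies on chromosome 6 at 98925338 to 99522721, minus strand, of mouse assembly GRCm38. Its level was 1.80 ± 0.0349 RPKM with the empty vector and 6.56 ± 0.71 with overexpression (SD, n = 3 each), a ratio of means of 3.64 (log2 fold change 1.43, limma adjusted p = 1.19e-09). The construct's species and untranslated regions are not stated, and this ratio counts only construct RNA that matches mouse exons, so it can be too low. It was 2.18 ± 0.0624 RPKM with the scrambled hairpin and 1.11 ± 0.0335 with the hairpin against Foxp1, a ratio of 0.508 (log2 fold change -0.59, adjusted p = 7.4e-06). Among related forkhead genes, Foxk1 rose with overexpression (log2 fold change 0.30, adjusted p = 0.00335) and Foxk2 fell with knockdown (-0.18, adjusted p = 0.00255). Foxk2 in overexpression (0.10, adjusted p = 0.0575), Foxk1 in knockdown (-0.17, adjusted p = 0.0625) and Foxp4 in either comparison (0.08 with adjusted p = 0.233 and -0.04 with 0.498) did not pass. Some of these crossed the threshold in other settings. With replicate number as a block, Foxk2 in overexpression reached adjusted p = 0.0487 and Foxk1 in knockdown 0.0159. Foxk2 in overexpression reached 0.0369 without overexpression replicate 3, and Foxp4 reached 0.0384 without overexpression replicate 1. Foxk1 in knockdown reached 0.0493 without scrambled replicate 3 and 0.00701 without knockdown replicate 2. Foxp2 was too low to test, with at most 0.00163 RPKM in any library.

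**Figure D1:**
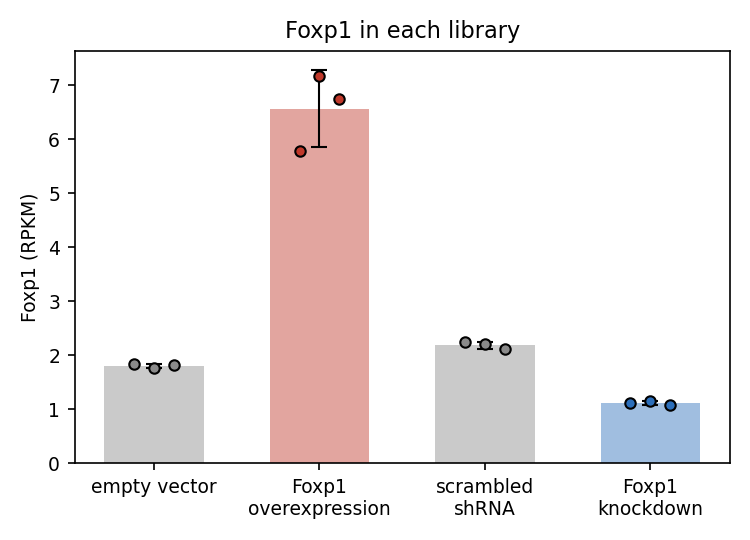
Foxp1 level in RPKM in each of the 12 libraries (points), with the mean (bars) and SD (error bars) of the 3 libraries per group. The means were 1.80 with the empty vector, 6.56 with overexpression, 2.18 with the scrambled hairpin and 1.11 with knockdown.

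The comparison of overexpression with the empty vector asks what a raised Foxp1 level changes in these fat cells, glycolysis above all, which the series title names. Glycolytic enzymes rose almost throughout the pathway, with 15 of 16 measured members up and 0 down. Several hallmark fat cell genes fell: adiponectin (Adipoq), the hormone secreted by mature fat cells, went from 1948 ± 17.3 to 437.5 ± 16.6 RPKM, and resistin (Retn) from 344.3 ± 6.05 to 77.6 ± 4.88 (SD, n = 3). Genes of cholesterol synthesis and targets of NRF2, the regulator of the oxidative stress response, fell as well. In all, 5775 of 11245 genes changed (51.4%), 3490 up and 2285 down, most of them by little. The median size of a called change was 0.28 on the log2(RPKM + 1) scale, and 352 genes rose and 282 fell by a ratio of 2 or more.

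Within glycolysis, enolase 1 (Eno1) rose from 33.9 ± 0.368 to 82.4 ± 3.34 RPKM (SD, n = 3; log2 fold change 1.26, SE 0.046, adjusted p = 4.39e-10). Phosphoglycerate kinase 1 (Pgk1) rose from 144.4 ± 3.46 to 297.8 ± 20.9 RPKM, lactate dehydrogenase A (Ldha), which turns pyruvate into lactate, from 288.2 ± 15.1 to 505.9 ± 11, and pyruvate kinase (Pkm) from 217.6 ± 5.47 to 345.2 ± 4.16. Eno3 (log2 fold change 1.25), Aldoa (0.74), Pfkp (0.69) and Gpi1 (0.66) rose too. The list had a median log2 fold change of 0.71 and passed camera (adjusted p = 1.56e-08), also with an estimated correlation (adjusted p = 0.00852). Adjusted over the list alone, 16 members rose. The member that did not pass over all genes was muscle phosphofructokinase (Pfkm), at 29.1 ± 0.209 and 32.4 ± 2.49 RPKM (adjusted p = 0.0596, or 0.00471 without overexpression replicate 3). Gapdh and Eno1 have processed pseudogenes, and how reads that match several places were counted is not stated, so their absolute levels are uncertain. Processed pseudogenes as a class, looked at after the main results, had 164 of 423 up and 17 down (median 0.25).

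**Figure D2:**
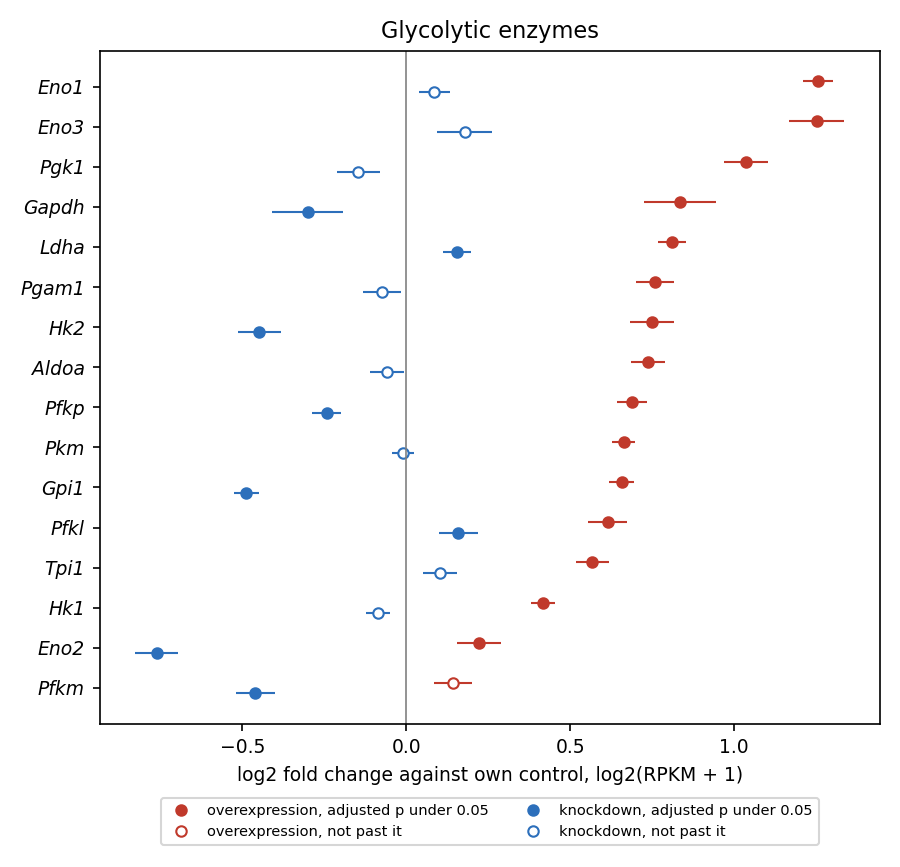
Log2 fold change of 16 glycolytic enzymes in overexpression (red) and knockdown (blue), each against its own control, on the log2(RPKM + 1) scale. Bars are limma standard errors, whose spread per gene comes from all 12 libraries (3 per group) and is the same for both comparisons. Filled points passed adjusted p of 0.05. The median was 0.71 in overexpression and -0.08 in knockdown.

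Genes beside glycolysis moved both ways. Of the list of glucose uptake, lactate handling and pyruvate dehydrogenase control, 10 of 19 members rose and 5 fell, and the list did not pass camera (adjusted p = 0.294). The lactate transporter Slc16a1 rose from 11.4 ± 0.451 to 22.4 ± 0.669 RPKM and pyruvate dehydrogenase kinase 4 (Pdk4) from 21.7 ± 1.31 to 49.6 ± 3.92, while Pfkfb3, which makes the activator of phosphofructokinase, fell from 17.7 ± 0.513 to 7.82 ± 0.555. Hypoxia targets outside glycolysis passed camera (median 0.60, adjusted p = 2.51e-04; adjusted p = 0.156 with an estimated correlation), with 14 of 19 up and 2 down. The prolyl hydroxylase Egln3 rose from 20.9 ± 1.44 to 51.7 ± 3.84 RPKM and the collagen hydroxylase P4ha1 from 14.4 ± 0.666 to 27.96 ± 1.82. The pentose phosphate list had 3 risen and 4 fallen of 8 (adjusted p = 0.357), among them Pgd (log2 fold change -0.58) and Tkt (0.62).

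Mature fat cell markers passed camera as a list (median -0.54, adjusted p = 2.82e-07; adjusted p = 0.0934 with an estimated correlation), with 14 of 18 down. The 2 members that rose were Pck1, an enzyme of glyceroneogenesis, from 1.995 ± 0.115 to 10.1 ± 0.897 RPKM, and the insulin-responsive glucose transporter Slc2a4, from 65.2 ± 1.06 to 83.0 ± 2.43. Genes listed as markers of undifferentiated preadipocytes did not move together, with 4 of 10 up and 4 down. Sox9 rose (log2 fold change 0.94) while Ly6a (-1.05) and Ebf1 (-0.58) fell. Whether each listed gene, Ebf1 among them, is confined to undifferentiated cells was not tested. The list had a median of 0.08 and a mean of 0.04, while camera placed it below other genes (adjusted p = 0.805). In fatty acid and triglyceride synthesis 11 of 17 fell and 4 rose, or 11 and 5 adjusted over the list alone (median -0.22, adjusted p = 0.00954; adjusted p = 0.544 with an estimated correlation). The desaturase Scd1 dropped from 5873 ± 208 to 2672 ± 31.5 RPKM and Thrsp from 590.6 ± 20.8 to 348.5 ± 15.5. In lipolysis and its adrenergic control 5 of 11 fell and 3 rose (median -0.08, adjusted p = 0.0362; adjusted p = 0.166 with an estimated correlation, 0.0521 with median-ratio scaling and 0.0525 with only the libraries compared). The adrenergic receptor Adrb3 went from 4.18 ± 0.379 to 0.273 ± 0.0399 RPKM, and hormone-sensitive lipase (Lipe) from 268.1 ± 3.53 to 135.5 ± 6.89. Thermogenic fat markers split, with 4 of 8 up and 3 down (adjusted p = 0.414). Cox8b rose from 48.4 ± 3.14 to 218.8 ± 18.4 RPKM and Cidea from 2.99 ± 0.729 to 12.7 ± 0.357.

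**Figure D3:**
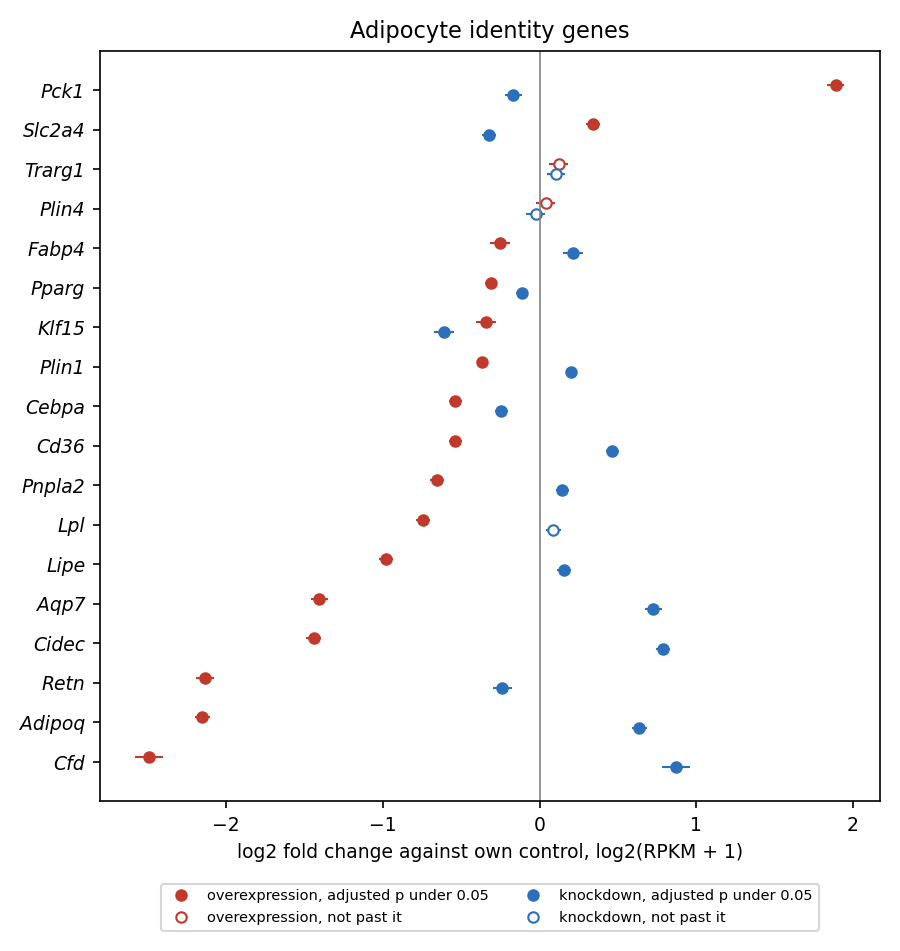
Log2 fold change of 18 adipocyte identity genes in overexpression (red) and knockdown (blue), each against its own control, on the log2(RPKM + 1) scale. Bars are limma standard errors, whose spread per gene comes from all 12 libraries (3 per group) and is the same for both comparisons. Filled points passed adjusted p of 0.05. In overexpression 14 of 18 fell, and in knockdown 9 rose and 6 fell.

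Cholesterol synthesis fell with a median of -0.61 (adjusted p = 7.97e-09; adjusted p = 0.00852 with an estimated correlation). There, 17 of 23 genes were down and 1 up, or 19 and 1 adjusted over the list alone. Lanosterol demethylase (Cyp51) went from 69.5 ± 1.85 to 26.5 ± 0.833 RPKM and Idi1 from 35.5 ± 0.465 to 19.1 ± 0.534. The riser, named after its values were seen, was squalene epoxidase (Sqle, 34.3 ± 0.513 to 45.01 ± 0.672). NRF2 targets had 13 of 15 down and 1 up (median -0.40, adjusted p = 1.13e-07; adjusted p = 0.0295 with an estimated correlation), including the glutathione transferases Gsta4 (31.4 ± 0.135 to 8.51 ± 0.573 RPKM) and Gsta3, and catalase (Cat, 275.8 ± 5.8 to 123.8 ± 2.12).

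Fatty acid oxidation had 11 of 18 up and 2 down, or 12 and 3 adjusted over the list alone (median 0.25, adjusted p = 0.0195; adjusted p = 0.623 with an estimated correlation), led by the thiolase Acaa2 (119.1 ± 1.4 to 269.2 ± 24.6 RPKM). The nuclear-encoded respiratory chain had 37 of 76 up and 0 down, or 35 adjusted over the list alone (median 0.16, adjusted p = 8.99e-04; adjusted p = 0.63 with an estimated correlation). Ndufv2 and Cox5a were among them (log2 fold changes 0.36 and 0.30). In the citric acid cycle list 11 of 19 rose and 4 fell, or 12 and 4 adjusted over the list alone (adjusted p = 0.142). Of 13 mitochondrially encoded messenger RNAs, 4 rose, or 3 adjusted over the list alone (median 0.34), and the list did not pass (adjusted p = 0.113). It did pass without overexpression replicate 2 (0.0435), with TPM (0.0362), with no filter on low values (0.0449), with a replicate block (0.0459) and with fry (0.0173). mt-Nd4l (log2 fold change 0.92), mt-Co1 (0.33) and mt-Co3 (0.56) were among the 4. The call of mt-Co1 ended under quantile normalization, which sets it to 0.00 because it had the highest value in every library. The call of mt-Co3 ended without empty vector replicate 2 (adjusted p = 0.0765) or 3 (0.0516) and without overexpression replicate 1 (0.0785) or 2 (0.0762). Ribosomal protein genes had 35 of 79 up and 0 down, or 26 adjusted over the list alone (median 0.18, adjusted p = 0.00357; adjusted p = 0.633 with an estimated correlation, and 0.0831 without overexpression replicate 1). Rpl3, Rpl35 and Rps26 rose by 0.36, 0.39 and 0.32. Levels of Rpl3 and mt-Co3 may be uncertain too, because how reads that match several places were counted is not stated.

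Cell cycle genes rose in 21 of 24 cases from low levels (median 0.26, adjusted p = 3.34e-04; adjusted p = 0.494 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, went from 1.89 ± 0.128 to 3.25 ± 0.24 RPKM. Extracellular matrix genes had 17 of 26 up and 4 down (median 0.24, adjusted p = 0.0249; adjusted p = 0.544 with an estimated correlation). Against that direction, decorin (Dcn) fell from 27.7 ± 2.03 to 7.99 ± 0.382 RPKM and lumican (Lum) from 7.07 ± 0.0472 to 1.98 ± 0.352. Inflammation genes had 6 of 11 up and 1 down (median 0.35, adjusted p = 0.0249; adjusted p = 0.156 with an estimated correlation). Lipocalin 2 (Lcn2) led them, at 82.7 ± 2.99 and then 708.9 ± 44.1 RPKM. Interferon response genes had 5 of 9 down and 0 up (median -0.23, adjusted p = 0.00183; adjusted p = 0.156 with an estimated correlation), with Gbp2 falling from 11.3 ± 0.407 to 1.28 ± 0.155 RPKM. ATF4 targets had 9 of 18 down and 4 up (median -0.22, adjusted p = 0.0249; adjusted p = 0.317 with an estimated correlation). The serine enzyme Psat1 fell from 110.8 ± 0.573 to 64.7 ± 1.88 RPKM while Fgf21 rose from 0.224 ± 0.0659 to 1.53 ± 0.135. Immediate early genes had 7 of 12 up and 1 down, or 8 and 1 adjusted over the list alone (median 0.27, adjusted p = 0.0305; adjusted p = 0.166 with an estimated correlation), with Fos at 0.953 ± 0.105 and 3.65 ± 0.18 RPKM.

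Other lists did not pass in overexpression. Insulin signalling had 9 of 19 up and 5 down (adjusted p = 0.777), with Foxo1 rising from 10.8 ± 0.155 to 22.2 ± 0.883 RPKM and Pde3b falling from 10.9 ± 0.681 to 3.78 ± 0.285. The unfolded protein response had 3 of 16 up and 4 down (adjusted p = 0.348), p53 targets 4 of 12 up and 6 down (adjusted p = 0.348) and replication-dependent histones 5 of 22 up and 2 down (adjusted p = 0.979). Markers of other cell types were mostly absent. Of skeletal muscle markers 3 of 12 were measured, with 2 up and 1 down, including Acta1 (13.04 ± 0.605 to 39.7 ± 3.14 RPKM). Of bone and cartilage markers 3 of 10 were measured, with 2 up and 1 down. Among these, the call of Runx2 ended without empty vector replicate 2 (adjusted p = 0.0929) or 3 (0.0978), without overexpression replicate 2 (0.116) or 3 (0.0641), and with a replicate block (0.0552). Of macrophage markers 2 of 13 were measured (1 down, Cd14), and of endothelial markers 0 of 8.

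The largest rises by log2 fold change, among genes with at least 5 RPKM on average, were in the transporter Slc45a3 (10.3 ± 0.499 to 123.7 ± 2.42 RPKM), mesothelin (Msln, 1.96 ± 0.214 to 26.3 ± 2.81), Lcn2, the cytochrome Cyp4b1 and Gm44386. The largest falls, within the same limit, were in the ubiquitin-like Ubd (33.1 ± 0.791 to 1.31 ± 0.157 RPKM), the desaturase Scd3 (24.3 ± 1.43 to 2.55 ± 0.0874), adipsin (Cfd, 1649 ± 60.9 to 293.9 ± 37.6), Gbp2 and Cyp2e1. In 6462 genes the groups did not overlap, where chance gives 10%. With libraries rescaled to TPM, 2437 genes rose and 2580 fell, so that the balance of small rises and falls depended on the scaling; without overexpression replicate 3 the count was 6221. Of the 26 lists tested, 16 passed camera (9 up and 7 down) and 3 with an estimated correlation.

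The comparison of knockdown with the scrambled hairpin asks the same of a lowered Foxp1 level. Genes of cholesterol synthesis and replication-dependent histones rose, and hypoxia targets outside glycolysis fell (adjusted p = 0.16 with an estimated correlation). Glycolysis did not stand out from other genes as a list. Several fat cell genes rose: Cidec, a lipid droplet protein, went from 2294 ± 42.4 to 3961 ± 166 RPKM and Adipoq from 910.2 ± 34.3 to 1416 ± 64.1 (SD, n = 3). Of 11245 genes, 5587 changed (49.7%), 2100 up and 3487 down, with a median called change of 0.26 on the log2(RPKM + 1) scale, and 104 rose and 89 fell by a ratio of 2 or more. The split into up and down was 2628 and 2955 with median-ratio scaling, 2650 and 2925 with quantile normalization and 1615 and 3710 with TPM.

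Of 16 glycolytic enzymes, 6 fell and 2 rose over all genes and adjusted over the list alone, with a median of -0.08. Camera gave adjusted p = 0.496, and fry, which asks whether the genes move one way on balance without comparing them with other genes, gave 5.65e-05 downward. Glucose-6-phosphate isomerase (Gpi1) fell from 280.3 ± 4.29 to 199.7 ± 4.47 RPKM, neuronal enolase (Eno2) from 3.01 ± 0.363 to 1.36 ± 0.0732, hexokinase 2 (Hk2) from 70.0 ± 3.28 to 51.1 ± 3.56 and Pfkm from 37.8 ± 2.79 to 27.1 ± 0.833. Pfkp fell by 0.24 on the log2 scale. Ldha rose, from 698.4 ± 13.8 to 778.2 ± 11.7 RPKM (adjusted p = 0.00989, or 0.061 with libraries rescaled to TPM). Gapdh (log2 fold change -0.30) and Pfkl (0.16) passed narrowly, at adjusted p = 0.036 and 0.0437. The call of Gapdh ended without scrambled replicate 1 (0.116) or 3 (0.0861) and without knockdown replicate 1 (0.0629), 2 (0.0725) or 3 (0.0921). That of Pfkl ended without any of the 6 libraries compared, at 0.0556 to 0.123.

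Next to glycolysis, 7 of 19 genes of glucose uptake, lactate handling and pyruvate dehydrogenase control fell and 3 rose (adjusted p = 0.326). Basigin (Bsg), the chaperone of lactate transporters, fell from 1414 ± 15.1 to 974.9 ± 13.2 RPKM and Pdk4 from 17.9 ± 0.291 to 10.0 ± 0.685. Of hypoxia targets 15 of 19 fell and 0 rose (median -0.36, adjusted p = 1.23e-05; adjusted p = 0.16 with an estimated correlation). Ndrg1 went from 6.02 ± 0.534 to 2.47 ± 0.0987 RPKM, and the carbonic anhydrases Car9 from 4.68 ± 0.106 to 2.31 ± 0.0564 and Car12 from 1.31 ± 0.134 to 0.322 ± 0.00826. In the pentose phosphate pathway 2 of 8 rose and 2 fell (adjusted p = 0.933), with Pgd up (log2 fold change 0.41) and Tkt down (-0.70).

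Cholesterol synthesis had 15 of 23 up and 3 down, or 17 and 3 adjusted over the list alone (median 0.31, adjusted p = 3.8e-06; adjusted p = 0.033 with an estimated correlation). Dhcr7 rose from 25.6 ± 0.763 to 41.4 ± 0.912 RPKM and Idi1 from 40.2 ± 2.05 to 59.6 ± 2.15. Cyp51, which fell in overexpression, fell here too, from 147.2 ± 3.88 to 125.3 ± 3.47 RPKM. NRF2 targets had 9 of 15 up and 2 down, or 9 and 3 adjusted over the list alone (median 0.21, adjusted p = 0.00115; adjusted p = 0.186 with an estimated correlation), including the cystine transporter Slc7a11 (0.479 ± 0.0257 to 1.39 ± 0.0336 RPKM), Cat and Nqo1. Transcripts of replication-dependent histones as a class mostly lack a poly(A) tail. Whether this holds for the measured members, which were taken by gene symbol, was not checked. Of these genes, 19 of 22 were up and 0 down (median 0.56, camera adjusted p = 2.39e-10, or 0.033 with an estimated correlation), for example Hist1h2bc (16.1 ± 2.24 to 30.1 ± 1.18 RPKM). Cell cycle genes had 20 of 24 up, or 22 adjusted over the list alone (median 0.20, adjusted p = 3.73e-06; adjusted p = 0.593 with an estimated correlation). Mcm5 went from 3.71 ± 0.142 to 4.84 ± 0.301 RPKM.

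Adipocyte identity genes had 9 of 18 up and 6 down (median 0.12, adjusted p = 0.0363; adjusted p = 0.743 with an estimated correlation). That call also ended without scrambled replicate 2 (0.0518) or 3 (0.0522) and without knockdown replicate 2 (0.0543), and with no filter (0.0655), median-ratio scaling (0.0719), quantile normalization (0.234), only the libraries compared (0.0534), array weights (0.0644) or reads outside the mitochondrial genome (0.0505). Besides Cidec and Adipoq, the water and glycerol channel Aqp7 rose from 3.28 ± 0.198 to 6.07 ± 0.415 RPKM. Preadipocyte markers had 2 of 10 up and 2 down (adjusted p = 0.809): Pdgfrb rose (log2 fold change 0.22) while Thy1 (-0.34) and Ly6a (-0.32) fell. Fatty acid and triglyceride synthesis had 6 of 17 up and 3 down, or 6 and 4 adjusted over the list alone (adjusted p = 0.547), with Dgat2 falling from 374.4 ± 8.32 to 241.6 ± 12.4 RPKM. Lipolysis had 4 of 11 up and 3 down (adjusted p = 0.547), with Mgll up by 0.39. Thermogenic markers had 5 of 8 down and 2 up (adjusted p = 0.278), with Cidea falling from 5.77 ± 0.487 to 1.303 ± 0.152 RPKM and Cox7a1 from 33.4 ± 1.18 to 19.0 ± 1.3. Fatty acid oxidation had 7 of 18 up and 1 down (median 0.07, adjusted p = 0.0217; adjusted p = 0.85 with an estimated correlation), with Cpt1a, the entry step into mitochondria, at 1.73 ± 0.0842 and 3.26 ± 0.0704 RPKM.

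Ribosomal protein genes had 11 of 79 up, or 2 adjusted over the list alone (median 0.06, adjusted p = 0.00378; adjusted p = 0.978 with an estimated correlation). Rpl7l1 rose from 27.9 ± 1.04 to 35.3 ± 1.65 RPKM. Extracellular matrix genes had 10 of 26 up and 6 down (median 0.07, adjusted p = 0.0363; adjusted p = 0.812 with an estimated correlation). That call ended without scrambled replicate 2 (0.0518) or knockdown replicate 1 (0.0645). Thrombospondin 1 (Thbs1) rose from 0.67 ± 0.0793 to 4.53 ± 0.209 RPKM. Of mitochondrially encoded messenger RNAs 3 of 13 rose, or 2 adjusted over the list alone (median 0.28, adjusted p = 0.0363; adjusted p = 0.812 with an estimated correlation). That list was not past the threshold without scrambled replicate 2 (0.14) or knockdown replicate 1 (0.0949), or with no filter (0.0655), median-ratio scaling (0.0868), quantile normalization (0.617), array weights (0.0658), fry (0.066) or reads outside the mitochondrial genome (0.0505). mt-Nd1 rose from 5868 ± 746 to 9557 ± 841 RPKM. The calls of mt-Nd2 and mt-Atp8, the other 2 that rose, ended without scrambled replicate 2 (0.0513 and 0.172) or knockdown replicate 1 (0.0506 and 0.131), and that of mt-Atp8 also without scrambled replicate 3 (0.0509) or knockdown replicate 2 (0.0937).

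Other lists did not pass in knockdown. The respiratory chain had 5 of 76 up and 10 down (adjusted p = 0.933), or 2 and 8 adjusted over the list alone, and the citric acid cycle 0 up and 6 of 19 down (adjusted p = 0.72), or 4 down adjusted over the list alone, with Idh2 at -0.31. Insulin signalling had 3 of 19 up and 8 down (adjusted p = 0.809), or 4 and 10 adjusted over the list alone; Foxo1 fell from 18.1 ± 0.195 to 10.9 ± 0.524 RPKM. Interferon response genes had 2 of 9 up and 4 down (adjusted p = 0.939), inflammation genes 2 of 11 up and 4 down, or 3 and 5 adjusted over the list alone (adjusted p = 0.98), ATF4 targets 4 of 18 up and 5 down (adjusted p = 0.723) and the unfolded protein response 4 of 16 up and 7 down (adjusted p = 0.98). Targets of p53 had 2 of 12 up and 3 down (adjusted p = 0.98), and immediate early genes 3 of 12 up and 3 down (adjusted p = 0.933). For the pentose phosphate, respiratory chain, preadipocyte, fatty acid synthesis, unfolded protein response and immediate early lists, the median lay below 0 while camera placed the list above other genes. Of inflammation genes, the mean lay above 0 while the median and camera lay below. Of the other cell type markers, muscle had 1 of 3 up and 2 down, bone and cartilage 2 of 3 down, and macrophage 1 of 2 down, Cd68. The call of Cd68 ended without scrambled replicate 2 (adjusted p = 0.175) or 3 (0.112) and without knockdown replicate 1 (0.161) or 3 (0.0951).

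The largest rises by log2 fold change in knockdown were ranked among genes with at least 5 RPKM on average and no overlap between groups. They were in Ubd (5.01 ± 0.55 to 31.8 ± 1.68 RPKM), the cornified envelope gene Sprr1a, the lipocalin Apod (4.37 ± 0.588 to 18.7 ± 2.16), the resistin-like Retnla (40.0 ± 4.02 to 135.7 ± 12) and smooth muscle actin (Acta2). The largest falls, within the same limits, were in Depp1 (22.3 ± 1.48 to 5.73 ± 0.828 RPKM), Porcn, which attaches lipid to Wnt proteins (63.5 ± 3.21 to 23.8 ± 2.11), Cyb561, the fatty acid receptor Ffar4 and Far2. In 6703 genes the groups did not overlap, where chance gives 10%. Of the 26 lists tested, 10 passed camera (9 up and 1 down) and 2 with an estimated correlation.

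**Figure D4:**
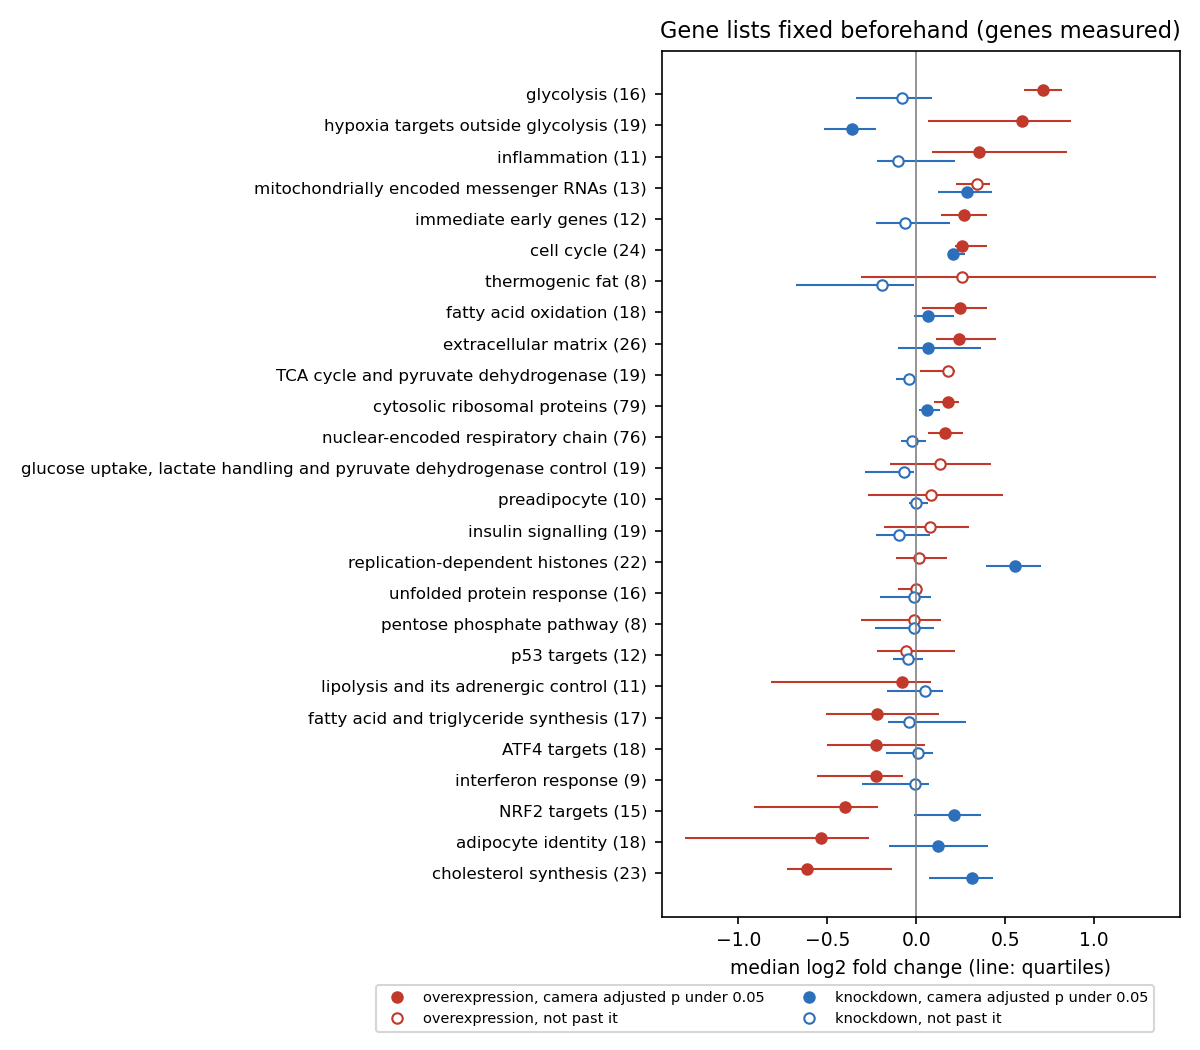
Median log2 fold change of 26 gene lists in overexpression (red) and knockdown (blue), each against its own control, on the log2(RPKM + 1) scale. Lines run from the lower to the upper quartile of each list, filled points passed camera at adjusted p of 0.05, and the number of measured genes stands after each name. Cholesterol synthesis had medians of -0.61 and 0.31, and hypoxia targets 0.60 and -0.36.

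The difference between both responses asks which genes respond unequally to more and to less Foxp1, and the calls of both show which respond in opposite ways. Genes with opposite calls outnumbered those with the same call: of 3217 genes called in both comparisons, 2035 (63.3%) moved in opposite directions and 1182 in the same direction. Ubd fell with overexpression and rose with knockdown (log2 fold changes -3.89 and 2.45), as did Retnla (-1.87 and 1.74). Dcaf4 (0.93 and -1.18), Fbln2 (0.77 and -1.04) and Kyat1 (0.79 and -1.07) rose with overexpression and fell with knockdown. Cyb561 (-1.06 and -1.31), Cdo1 (-0.72 and -0.69) and Gchfr (-1.01 and -1.04) fell in both, and Htra3 (0.55 and 0.80) and Serpinb9 (0.81 and 0.83) rose in both.

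If calls were independent, 1509 opposite and 1360 same calls would result. The 1360 genes up with overexpression and down with knockdown compare with 1082.2 in independent lists (Fisher's exact test, adjusted p = 1.96e-33 over 4 tests), and the 675 down and up with 426.7 (adjusted p = 1.15e-45). Both groups of same calls lay below independence, 531 genes up in both beside 651.8 (adjusted p = 2.23e-10) and 651 down in both beside 708.6 (adjusted p = 0.00357). Genes are not independent of each other, so these p-values are too small. Across genes the log2 fold changes correlated at r = -0.204 (Spearman -0.143), and the comparisons shared no control libraries. The difference itself passed for 6173 genes, 3888 higher and 2285 lower in overexpression; the split was 3149 and 2909 with median-ratio scaling and 3069 and 2989 with quantile normalization.

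The control groups, empty vector and scrambled hairpin, differed from each other more than either did from its Foxp1 group by count. Hypoxia and glycolysis genes and cell cycle genes were higher in the scrambled group, and histones and mitochondrially encoded messenger RNAs lower. The cell cycle and mitochondrial calls ended with an estimated correlation (adjusted p = 0.3 and 0.349). The AP-1 member Fosl1 stood at 2.04 ± 0.124 RPKM with the empty vector and 77.6 ± 2.7 with the scrambled hairpin (SD, n = 3), and Ghrh at 11.1 ± 1.63 and 189.3 ± 12.8. Orm2 stood at means of 126.8 and 4.69, Apod at 107.3 ± 7.73 and 4.37 ± 0.588, and Cox8b at 48.4 ± 3.14 and 3.19 ± 0.237.

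Of 11245 genes, 8070 differed between the control groups (71.8%), 5037 higher and 3033 lower in the scrambled group; with quantile normalization the split was 4045 and 3893. Glycolysis had 15 of 16 higher (median 1.21, camera adjusted p = 4.58e-06, or 0.0275 with an estimated correlation) and hypoxia targets 18 of 19 (median 1.94, adjusted p = 1.24e-08, or 0.0489 with an estimated correlation). Both medians were larger than those of the same lists in overexpression (0.71 and 0.60), although neither control targets Foxp1. Foxp1 itself was also higher with the scrambled hairpin, at 2.114 to 2.235 RPKM per library beside 1.765 to 1.831 with the empty vector. Whether that difference plays a part was not tested. Cell cycle genes had 24 of 24 higher (median 1.23, adjusted p = 1.24e-08; adjusted p = 0.3 with an estimated correlation). Histones had 22 of 22 lower (median -1.09, adjusted p = 9.92e-11; adjusted p = 0.0275 with an estimated correlation), and mitochondrially encoded messenger RNAs 11 of 13 (median -0.96, adjusted p = 3.43e-04; adjusted p = 0.349 with an estimated correlation). Ribosomal protein genes (median 0.33) and the unfolded protein response (0.56) were higher with the scrambled hairpin, and NRF2 targets (-0.72), fatty acid synthesis (-0.48), fatty acid oxidation (-0.35), adipocyte identity (-0.33), the citric acid cycle (-0.18) and the respiratory chain (-0.05) lower. Their adjusted p with an estimated correlation were 0.639, 0.349, 0.0873, 0.448, 0.448, 0.3, 0.448 and 0.759 in that order. Of the lists tested, 13 passed camera and 3 with an estimated correlation. Experiment and vector type are mixed in this comparison, and values of the overexpression and knockdown groups are compared here only through their own controls.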

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

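The tests of fat cell markers and histones below were chosen after the results were seen; the relabelling of libraries was planned, except the exchange of the knockdown groups and the judgement on opposite calls.

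The response to overexpression differed from that to knockdown, by a test of the difference itself, in 6173 genes. Among 100 of 200 possible relabellings of the libraries within both experiments, the real one gave the highest count (1 of 100), the next 2556. This argues against a random assignment of libraries with no response in either experiment. A response in only 1 experiment could rank first as well, so the rank does not show that the responses differ. Chance between cultures or transductions was not tested, since what a replicate is is not stated. The draw did not include the real groups with the knockdown groups exchanged, which gave 5377. For the 2035 opposite calls (1 of 100, next 0) the relabelling decides nothing, because none of the other draws called genes in both experiments. Glycolysis (median difference 0.88, 16 of 16 higher in overexpression, adjusted p = 1.69e-07; adjusted p = 0.0116 with an estimated correlation) and hypoxia targets (1.03, adjusted p = 6.67e-07; adjusted p = 0.0574 with an estimated correlation) differed upward. Cholesterol synthesis (-0.74, adjusted p = 1.06e-11; adjusted p = 0.00668 with an estimated correlation), NRF2 targets (-0.63, adjusted p = 3.27e-09; adjusted p = 0.0158 with an estimated correlation) and histones (-0.52, adjusted p = 1.55e-06; adjusted p = 0.0574 with an estimated correlation) differed downward. So did adipocyte identity (-0.69, adjusted p = 2.08e-06; adjusted p = 0.0914 with an estimated correlation), fatty acid and triglyceride synthesis (-0.31, adjusted p = 0.0112; adjusted p = 0.58 with an estimated correlation), ATF4 targets (-0.25, adjusted p = 0.0179; adjusted p = 0.287 with an estimated correlation) and lipolysis (-0.13, adjusted p = 0.0488; adjusted p = 0.178 with an estimated correlation). The respiratory chain differed upward by 0.17 (adjusted p = 0.0396; adjusted p = 0.87 with an estimated correlation). Of single genes with opposite calls, Ubd differed by -6.34, Retnla by -3.61, Dcaf4 by 2.11, Kyat1 by 1.86 and Fbln2 by 1.81 on the log2 scale.

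Fat cell markers fell with overexpression (adjusted p = 0.0934 for the list with an estimated correlation). If a lower share of differentiated cells raised all markers of undifferentiated cells, the preadipocyte markers should not fall, but 4 of the 10 measured fell and 4 rose. That premise was not tested, nor was it tested whether each listed marker is confined to undifferentiated cells. Cell cycle genes (21 of 24 up) and extracellular matrix genes (17 of 26 up and 4 down) rose in the same comparison, though not with an estimated correlation (adjusted p = 0.494 and 0.544). The values go both ways, so a lower share of differentiated cells cannot be judged from them. Scaling between libraries is argued against, since the scaling that brought the list nearest to 0 still left a median of -0.41. What underlies the fall stays open, and the number of independent transductions behind it is unknown.

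Histone transcripts rose with knockdown and were lower in the scrambled than in the empty vector group. As a class they mostly lack a poly(A) tail, which was not checked for the measured members. A trend with transcript length is argued against in knockdown, where other genes of that length range had a median of -0.004. Small nucleolar RNAs rose in knockdown too (median 0.47, 17 of 46 up) and were at 0.086 between the control groups. How well the columns and libraries kept such RNAs is not stated, and whether they gauge RNA without a poly(A) tail was not checked. More RNA without a tail therefore cannot be judged from them in either comparison. More cells in cycle may account for the rise in knockdown (cell cycle list 0.20, camera adjusted p = 0.593 with an estimated correlation). In overexpression, however, cell cycle genes rose by 0.26 (adjusted p = 0.494 with an estimated correlation) with 5 of 22 histones up and 2 down. Between the control groups more cells in cycle is argued against as the whole cause, because cell cycle genes were at 1.23, not below 0. How RNA was selected for sequencing is not stated, so what sets histone levels between the experiments stays open.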

How the results depend on the processing

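The alternatives with reads outside the mitochondrial genome and with voom were chosen after seeing the data. At a fold of at least 1.5, 954 genes passed in overexpression, 390 in knockdown, 1685 for the difference, 1961 between controls and 112 with opposite calls. At adjusted p under 0.01, 10 lists passed in overexpression, 6 in knockdown, and 1303 genes had opposite calls. Quantile normalization left 5 knockdown lists, and camera with an estimated correlation 3 lists in overexpression and 2 in knockdown; fry passed glycolysis in knockdown (-0.08), a test of another question. The cause of the quantile result was not tested. Without 1 library, counts ranged from 4965 to 6221 in overexpression, 4758 to 5350 in knockdown, 5696 to 6678 for the difference, 7542 to 7632 between controls and 1747 to 2294 with opposite calls, lists from 15 to 17 and 7 to 10, and glycolysis medians from 0.668 to 0.735 and -0.10 to -0.07. Replicate numbers showed no clear pairing of the samples: same-numbered libraries deviated at r = -0.01, 0.12 and 0.08 in overexpression and -0.07, 0.05 and -0.06 in knockdown. Differently numbered libraries reached 0.24 and -0.19 in knockdown, and pairing under other numbers was not tested. With a replicate block, 5688 genes passed in overexpression, 5498 in knockdown, 6117 for the difference and 8048 between controls, and with voom 5784, 5695, 6162 and 8031. Array weights also passed Foxk2 (0.0129) and Pfkm (0.00375) in overexpression and Foxk1 (0.0216) in knockdown. Of 156 gene values, 141 kept direction and side in every alternative except the fold threshold, and none turned; mt-Co1 in overexpression was set to 0.00 by quantile normalization (through its rank as the highest gene in every library). Calls of narrow size ended in other ways too. With no filter on low values, mt-Nd1 (adjusted p = 0.0976) and mt-Nd2 (0.0982) in knockdown and mt-Co1 (0.663) and mt-Co3 (0.069) in overexpression did not pass, and neither did Gapdh (0.12), Pfkl (0.11), Cd68 (0.142) and mt-Atp8 (0.186) in knockdown or Runx2 (0.0659) in overexpression. Quantile normalization ended the calls of ATF4 targets (0.068) and lipolysis (0.0964) in overexpression and of adipocyte identity (0.234), ribosomal proteins (0.0618; 0.392 with fry), extracellular matrix (0.241), fatty acid oxidation (0.0618; 0.0537 with fry) and mitochondrially encoded messenger RNAs (0.617) in knockdown. A filter at 5 RPKM ended those of extracellular matrix (0.0557), immediate early genes (0.184) and lipolysis (0.183) in overexpression and of extracellular matrix (0.171) in knockdown. Of the alternatives, the 7 lists added later were given only camera with an estimated correlation, and the gene classes none. None of 27 medians printed for lists fixed beforehand in overexpression and knockdown changed sign, but sizes moved. For example, histones in knockdown went to 0.172 with a pseudocount of 5, 0.122 with no filter and 1.149 with voom. In overexpression, cell cycle went to 0.11 and hypoxia targets to 0.278 with a pseudocount of 5, and cell cycle to 0.577 with voom. Inflammation went to 0.087 and interferon response to -0.073 with no filter. Without 1 library, medians in overexpression ranged from 0.023 to 0.14 for preadipocyte markers, -0.118 to -0.042 for lipolysis and 0.212 to 0.393 for mitochondrially encoded messenger RNAs. Ribosomal proteins ranged from 0.109 to 0.24 in overexpression and 0.032 to 0.103 in knockdown. Other lists that did not pass are given in the text without medians: 3 of 8 in overexpression and 8 of 15 in knockdown changed sign somewhere, and 7 and 5 passed somewhere. This limit on medians was set after seeing those sign changes. Small changes can be missed: 17 of 50 simulated 1.2-fold changes were found in overexpression and 11 of 50 in knockdown. The simulation changed only a small share of the genes, while 51.4% and 49.7% of genes were called in the real data. Its adjusted threshold was therefore stricter, and these shares may not apply to the real comparisons.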

Other observations

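The 7 lists and the clock test below were chosen after the main results were seen, while the counts of splits were planned. Genes of the circadian clock fell in knockdown, 12 of 15 down and 1 up (median -0.46, adjusted p = 7.94e-04 over 33 lists; adjusted p = 0.498 with an estimated correlation). The output regulator Dbp went from 25.1 ± 1.38 to 11.2 ± 0.478 RPKM, Nr1d1 from 36.6 ± 1.99 to 23.8 ± 1.39 and Per3 from 4.33 ± 0.398 to 2.51 ± 0.202 (SD, n = 3), while the activator Arntl rose from 2.42 ± 0.0482 to 3.10 ± 0.168. In overexpression 5 of 15 rose and 6 fell (adjusted p = 0.64), Dbp (-0.34), Nr1d1 (-0.54), Per3 (-0.40) and Arntl (0.32) in the same direction as in knockdown, and Bhlhe40 (0.74, and -0.58 in knockdown) and Ciart (0.39 and -0.54) in opposite directions. The responses differed in 10 of 15, all higher in overexpression (adjusted p = 0.0386; adjusted p = 0.615 with an estimated correlation). Genes of caveolae, the membrane pits common in fat cells, had 6 of 7 up in knockdown (median 0.22, adjusted p = 9.56e-04; adjusted p = 0.0621 with an estimated correlation), with Cavin3 at 62.3 ± 4.87 and 103.0 ± 8.71 RPKM. In overexpression they had 2 up and 2 down, or 2 and 3 adjusted over the list alone (adjusted p = 0.666).

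Breakdown of branched-chain amino acids had 11 of 18 down and 2 up in overexpression (median -0.14, adjusted p = 0.011; adjusted p = 0.604 with an estimated correlation) and 10 down and 2 up in knockdown (adjusted p = 0.153). Peroxisome genes had 7 of 17 down and 3 up in overexpression, or 9 and 3 adjusted over the list alone (adjusted p = 0.0249; adjusted p = 0.51 with an estimated correlation). In knockdown, de novo purine synthesis had 7 of 11 up and 3 down (adjusted p = 0.0354; adjusted p = 0.415 with an estimated correlation), glycogen metabolism 9 of 15 down and 1 up (adjusted p = 0.0486; adjusted p = 0.695 with an estimated correlation) and lysosome genes 10 of 20 down (adjusted p = 0.0667). Between controls, 15 of 20 lysosome genes were lower with the scrambled hairpin (adjusted p = 1.96e-04; adjusted p = 0.101 with an estimated correlation).

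A harvest at another phase of the clock may account for the fall of clock genes, since activators and the genes they drive peak at opposite phases. The 9 measured driven genes had a median of -0.50 and the 2 measured activators 0.10, opposite in sign. But of the activators only Arntl passed, with Clock at 7.05 ± 0.102 and 6.80 ± 0.624 RPKM (adjusted p = 0.498), so a shifted phase cannot be told apart from a lower clock output. The requirement that the activators move alike was added after these values were seen; without it the signs would have counted for a shift. Harvest times are not given.

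Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. The real split called 5775 genes in overexpression, 5587 in knockdown and 8070 between controls, and the highest of the others 0 in each, so that 1 of the 10 splits gave as many. Of lists, the real split called 16 in overexpression beside at most 11 in another split, and 10 in knockdown beside 9. The other 9 splits called 5 to 11 lists in overexpression and 2 to 9 in knockdown, while calling 0 genes. Each of these splits mixes libraries of both groups, so it keeps part of the real difference and adds the rest to the spread within groups. Their gene counts were thus bound to be low, and their lists are no measure of chance. The glycolysis median was 0.71 beside -0.29 in overexpression and -0.08 beside -0.06 in knockdown.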
